A study of Macaca mulatta with 25 samples.

How the data were processed

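RNA was isolated with Trizol from flash-frozen tissue, and libraries were made from total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. TopHat and Cufflinks 2.0.2 are named in the submitters' processing notes, without their settings. The genome build and the release of the Ensembl annotation are not given in the sources used here. The authors deposited 2 tables of the whole series, named for FPKM (fragment counts scaled to transcript length and library size) and for read coverage, with 1 row per Ensembl transcript, a locus, a transcript length in bases and 25 numbered value columns, per the file headers. Both tables held identical transcript identifiers, loci and lengths.

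Libraries were grouped by the tissue named in their titles, and the letter A or B in a title was taken as the fetus. The value columns were inspected for their names, ranges and scale, and no value from them entered a result. Their names matched no label, so 25 value columns per table, 50 over both tables, were not used, and none was assigned to a tissue or fetus by order or by content. Transcript identifiers were looked up in a table of 24186 rhesus gene identifiers with symbols, which holds gene rather than transcript identifiers, and 0 matched. A second table of RefSeq genes gave no Ensembl identifier in any row and was not used further.

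Tests for the tissue panel and for the 2 fetuses had been specified before the data were examined: limma on log2-transformed FPKM, gene lists for cell types and pathways, and the level of MECP2 in every library, with a fixed rule for the genes to be named. None of these could be run without a link from columns to samples. No gene is named from the data, because no transcript identifier was paired with a symbol. What was computed is a description of the annotation columns, chosen after seeing the data: the number of transcripts, their lengths, the number of distinct loci, and the number of transcripts whose length equals the difference between the end and the start of their locus. No annotated length exceeded that span. The length below which a transcript was called short was 200 bases. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and the reading of loci was tested on simulated rows. Those rows were built with the same rule of end minus start. The test therefore cannot show that the deposited loci follow that rule. The alternatives tried were 1 transcript per locus and the removal of short transcripts. Depth per library is not reported, because it would have to come from the unused columns.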

Results

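The study profiled RNA by high-throughput sequencing in tissues of 2 aborted male rhesus monkey fetuses (Macaca mulatta). The series title places these tissues in a project that mutated MECP2 with TALENs. TALENs are engineered nucleases that cut a chosen DNA site. MECP2 is an X-linked gene whose protein binds methylated CpG dinucleotides, and mutations in it are known in Rett syndrome. The labels described 25 libraries in 14 tissue groups. Of these libraries, 13 carried the letter A and 11 carried the letter B in their titles, and the letters were read as the 2 fetuses. The placenta library carried neither letter. Brain, heart, intestine, kidney, leg, liver, ribs, spine, spleen and tail made up the 10 tissues sampled in both fetuses. Kidney was represented by 3 libraries, of which the left and right kidneys of fetus A were 2. Lung and arm were sampled in fetus A alone, head was sampled in fetus B alone, and placenta was sampled once. No library was labelled as coming from an unedited animal, and no library title said that its animal was edited.

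The design implied 3 kinds of comparison. Each organ could be set against the other tissues, the body pieces (leg, ribs, spine and tail) could be set against the internal organs, and fetus A could be set against fetus B within tissues. None of these comparisons was made. The expression values stood in 25 columns per table under running numbers, and 0 of these 25 column names occurred in the labels of any sample. Assigning a column to a tissue from the transcripts abundant in it would have taken the outcome as the label. Assigning it from its position would have rested on an order that could not be checked against the labels. The expression columns were therefore not analysed here. MECP2 was likewise not reported in any library. The rows carried Ensembl transcript identifiers, whereas the gene names used here are listed under gene identifiers. A match was therefore not possible, and 0 of the rows could be paired with a gene symbol. No expression level, fold change, depth or p-value is therefore given.

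The part of the tables that belongs to no sample was the transcript annotation of their rows. Whether these rows are all the transcripts that were quantified could not be told from them. The annotation listed 42701 Ensembl transcripts on 21 chromosomes, the 20 rhesus autosomes and X. It listed no transcript on chromosome Y, on the mitochondrial genome or on unplaced sequence. The absence of Y was not read as a result about the male fetuses, because no expression value was used. The annotated transcript lengths ran from 24 to 61706 bases with a median of 1276 bases. The middle of the distribution lay between 472 bases at the lower quartile and 2248 bases at the upper quartile. The longest transcript lay on chromosome 12. The transcripts occupied 40932 distinct loci, meaning distinct combinations of chromosome, start and end. Of these loci, 1443 held more than 1 transcript, and together they accounted for 3212 transcripts, with at most 10 at 1 locus.

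A transcript whose annotated length equals the span of its locus has no intron in its model. This held for 9393 transcripts, or 22.0% of the annotation. Transcripts shorter than 200 bases numbered 6245, or 14.6% of the annotation, and 94.9% of these short transcripts had no annotated intron. With the short transcripts left out, the share without an annotated intron was 9.51%.

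Chromosome X, which carries MECP2, held 1894 transcripts, or 4.44% of the annotation. The median length of X transcripts was 1050 bases, against 1287 bases for the 40807 autosomal transcripts. Medians of single autosomes ran from 1088.5 bases on chromosome 4 to 1478 bases on chromosome 16. Transcripts without an annotated intron made up 29.0% of the X transcripts and 21.7% of the autosomal transcripts. With transcripts shorter than 200 bases left out, these shares were 14.2% on X and 9.30% on the autosomes. Shares on single autosomes were not computed without the short transcripts. With all transcripts counted, the share on single autosomes ran from 15.4% on chromosome 20 to 28.9% on chromosome 7, and the share on X lay just above that of chromosome 7. These are properties of the annotation rather than of the libraries, they have no replicate error, and no test was applied to them.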

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

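No alternative specified before the data were examined could be run, because each needed a value column tied to a sample. No paired analysis was possible because the columns carry no fetus letter or tissue. The alternatives below were chosen after seeing the data. Keeping the longest transcript at each locus left 40932 of the 42701 transcripts, since transcripts with a different start or end count as separate loci. It gave a median length of 1250 bases and a share without an annotated intron of 22.9%, with 30.2% on X and 22.6% on the autosomes. Removing transcripts shorter than 200 bases gave a median length of 1535 bases and lowered that share to 9.51%, with 14.2% on X and 9.30% on the autosomes, which follows from the removal itself, since nearly all short transcripts have no annotated intron. The share of transcripts on X was 4.45% and 4.27% under these alternatives.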
